A study of Caenorhabditis elegans with 6 samples.

How the data were processed

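Whole-body RNA of synchronized adult Caenorhabditis elegans was sequenced in 6 libraries, 3 from worms fed Escherichia coli BW25113 and 3 from worms fed the strain named purE, and each library was assigned to its group and replicate number by its label. Estimated counts per gene were deposited as read counts, per the file headers, and between 91.0% and 92.2% of the values in a library were whole numbers. FPKM values were deposited beside them, per the file headers, as counts scaled by the authors to gene length and library size. The genome build was WBcel235, per the submitters' processing notes. The aligner, the counting tool and the strand setting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may have been divided in ways that cannot be checked. Replicates were deposited as separate columns.

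Estimated counts were rounded to whole numbers. The files held 18811 genes, of which 18791 were protein coding and 1202 had no read in any library. Coordinates came from an annotation of the same build matched by gene identifier for 18799 genes, and exon length was known for all 18811. Genes were kept with the default expression filter of edgeR, which left 12144. Libraries were scaled with TMM factors, which ranged from 0.844 to 1.20, and the 100 most abundant genes held between 42.6% and 47.8% of the counts of a library. The biological coefficient of variation was 0.407.

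The purE group was compared with the BW25113 group with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. Log2 CPM values used a prior count of 2. Of the 35 gene lists fixed beforehand, 34 were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, with at least 5 tested members required, and the list of mitochondrially encoded genes was not analysed here. Counts of called members were also computed adjusted over the list alone. The camera test was repeated with the correlation estimated from the data, and fry tested whether the genes of a list move without comparing them with other genes. The gene lists, the naming rule, the tests and the alternatives were chosen before the data were examined, except where stated.

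Under the naming rule the genes named were those with the largest fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups. Since no gene was called, the rule's substitute applied, which takes the 5 largest per direction among genes with an unadjusted p under 0.001 that meet the same conditions. From each list the rule took called members or, with none called, the member of smallest p, and 13 stress, metabolism and immunity reporters were named in any case.

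The alternatives were no low-count filter, a filter of at least 1 CPM in 3 libraries, other scalings (size factors of DESeq2, library size alone, upper quartile), DESeq2 1.42.0, limma-voom, the replicate number as a block, a minimum fold of 1.5, the 100 most abundant genes left out and each library left out in turn. Alternatives added after seeing the data were a robust and an older form of the edgeR test, limma on log2(FPKM + 1) of the deposited FPKM values with at least 1 FPKM in 3 libraries, DESeq2 with each library left out, lists without the 100 most abundant genes, and a covariate made of the mean log2 CPM of the sperm markers.

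The procedures were tested on simulated data for the comparison of purE with BW25113, with counts drawn from the means, library sizes and dispersions of these libraries and 200 genes changed. With the estimated dispersion and 11906 genes tested, edgeR recovered 1.54% of genes changed 2-fold, 41.5% of those changed 4-fold and 84.4% of those changed 8-fold, and 3 of its 85 calls were false. DESeq2 recovered 7.69%, 73.8% and 95.3%, and 33 of its 147 calls were false, or 22.4%. limma-voom recovered 1.54%, 36.9% and 85.9%, with 5 of 85 calls false. With 0.1 of that dispersion edgeR recovered 79.4%, 100% and 100% over 11991 genes. Of 5 simulated lists shifted 1.5-fold among 20, camera with the preset correlation called 5, camera with an estimated correlation 2 and fry 3, with 0 unshifted lists called by any of them, over 11939 genes. Simulated genes were drawn independently, whereas the correlation estimated in the real lists reached 0.904 for sperm markers and 0.94 for vitellogenins. The simulation therefore cannot show how often camera with the preset correlation calls such lists falsely. Its shares of false calls come from a single draw per dispersion and need not hold for the real calls.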

Results

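The transcriptome of whole Caenorhabditis elegans was measured by RNA sequencing in adult worms kept on 1 of 2 bacterial diets. The worms grew at 20 °C and were moved at larval stage 4 onto plates seeded with Escherichia coli BW25113, a common laboratory strain, or with the strain named purE in the labels. The bacterial gene purE encodes an enzyme of purine synthesis, and the labels do not say how the strain was altered. Each diet had 3 libraries, and the total estimated count per library ranged from 21880610 in purE replicate 2 to 22607925 in purE replicate 1. The labels say nothing on whether the replicates were separate cultures of worms, so every p-value below measures the spread between these samples only. That spread was beyond counting error, with a chi-square per degree of freedom of 42.5 to 350 between libraries of the same diet. Whether other technical sources added to it is not known. A value of 3 counts, the most that a count of 0 allows, corresponded to between 0.133 and 0.137 CPM (the count scaled to library size), a limit that covers counting error only.

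The series asks how bacterial genes influence the life span of the host, and the comparison was purE-fed over BW25113-fed worms. The gene lists with the smallest camera adjusted p were markers of sperm and the cuticle collagens, both higher on the purE diet, and markers of the early embryo and of oocytes, both lower. Their median log2 fold changes were 2.83, 3.04, -0.91 and -0.39. Genes of purine synthesis and salvage and of the folate and methionine cycles were higher as groups, with medians of 0.40 and 0.39. For each of these 6 lists the adjusted p = 0.849 with an estimated correlation, and the self-contained test fry called 0 of all 34 lists by direction and 4 in either direction. Among single genes, argk-1, an arginine kinase, averaged 9.60 ± 2.69 CPM on BW25113 and 57.4 ± 7.05 CPM on purE (SD, n = 3), and cth-1, a cystathionine gamma-lyase, averaged 22.8 ± 7.73 and 125 ± 20.5 CPM (SD, n = 3). No single gene passed the adjusted threshold in edgeR's quasi-likelihood test: 0 of 12144 genes were called, with a smallest Benjamini-Hochberg adjusted p of 0.129. An unadjusted p under 0.05 was found for 2004 genes, where chance alone gives 607 on average. Groupings of the same libraries with mixed diets gave from 20 to 2218 such genes, so the excess is not evidence of a diet effect. DESeq2 called 946 genes, 760 higher and 186 lower on purE, and limma-voom called 0, with 1560 genes at an unadjusted p under 0.05. On counts simulated for this comparison with 11906 genes tested, 22.4% of DESeq2's calls were false, against 3.53% of edgeR's. Of the 2004 genes, 1541 were higher and 463 lower on purE, or 76.9% higher. That share was 68.7% with the 100 most abundant genes left out and 55.5% without purE replicate 1, with 2373 genes higher and 1900 lower.

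The libraries of the purE group were not alike. The first principal component of log2 CPM held 69.3% of the variance and placed purE replicate 2 at 120 and purE replicate 3 at 50.8, with purE replicate 1 at -26.02 beside the BW25113 libraries at -39.7, -45.5 and -59.8. Across genes, which are not independent replicates, purE replicate 1 had a correlation of 0.978 with BW25113 replicate 3, against 0.860 and 0.952 with the other purE libraries. Without purE replicate 1, edgeR called 1852 genes, of which 901 were among the 946 that DESeq2 called on all libraries, and DESeq2 then called 2574. DESeq2 called 365 genes without BW25113 replicate 1, 303 without BW25113 replicate 2, 992 without BW25113 replicate 3, 259 without purE replicate 2 and 519 without purE replicate 3. With the mean of the sperm markers as a covariate, an alternative chosen after the result was seen, 313 genes had an unadjusted p under 0.05, 62 higher and 251 lower or 19.8% higher, and camera called 3 of the other 33 lists, the purine genes as higher and the collagens and epidermal antimicrobial peptides as lower. For each of the 3 under the covariate the adjusted p = 0.933 with an estimated correlation. All purE libraries lay above all BW25113 libraries for 1593 genes, 13.1% of those tested, and below for 811, or 6.68%, where chance gives 10% on average for both directions together.

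**Figure D1:**
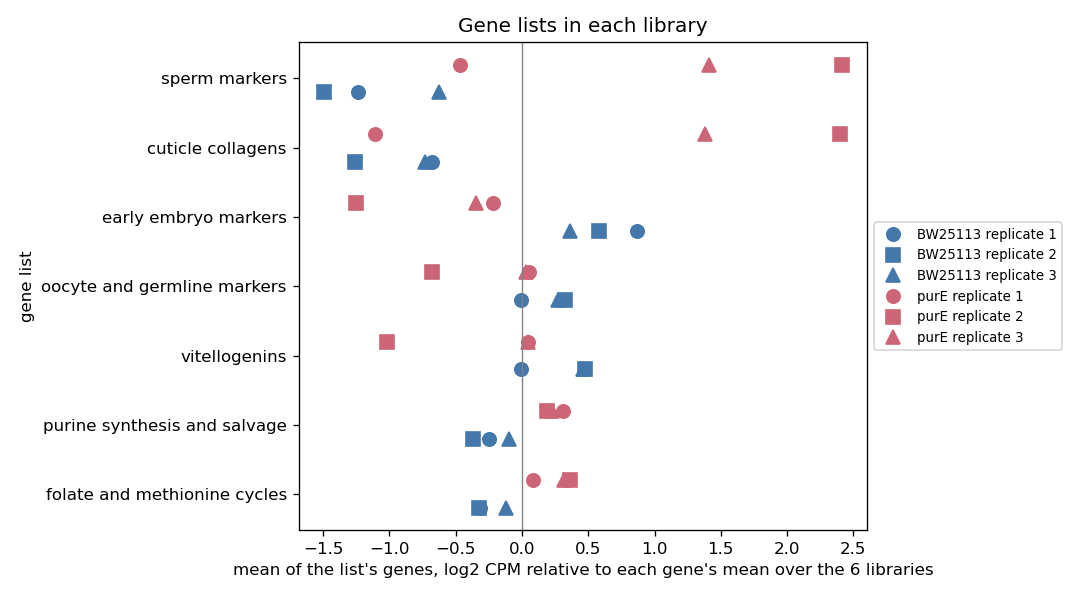
The plot shows, for 7 gene lists, the mean log2 CPM of the list's genes in each library relative to each gene's mean over the 6 libraries, with BW25113 in blue, purE in red and 1 symbol per replicate number. The collagen value of purE replicate 1, -1.11, lies within the range of the BW25113 libraries, and its sperm value, -0.46, lies near that range but above it. The purine values of all 3 purE libraries, 0.19 to 0.31, lie above all of the BW25113 values, -0.37 to -0.10.

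Sperm markers rose as a group on the purE diet. All 21 tested members had a positive log2 fold change, with a median of 2.83, and 20 of them were called higher when adjusted over the list alone, against 0 over all genes tested in edgeR, 20 at an unadjusted p under 0.05 and 16 in DESeq2. The major sperm protein gene msp-3 (chromosome II, 4785898 to 4786281) averaged 13.3 ± 3.20 CPM on BW25113 and 111 ± 94.2 CPM on purE (SD, n = 3), a log2 fold change of 3.06 ± 0.67 (SE), or 2.2 without purE replicate 2. The phosphatase gene gsp-3, chosen after its values were seen, had a log2 fold change of 2.75 ± 0.64. The camera test of the list gave an adjusted p of 3.74e-10, and an adjusted p = 0.849 with an estimated correlation. Members of the major sperm protein family are near-identical copies whose reads may have been divided between them, so values of single members are uncertain. The per-library means of the list were 2.41 in purE replicate 2 and 1.41 in purE replicate 3. The mean in purE replicate 1 was only -0.46, yet above the range of -0.62 to -1.49 on BW25113. For 17 of the 21 members all purE libraries lay above all BW25113 libraries.

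Cuticle collagens also rose as a group, though only in purE replicates 2 and 3. Of 129 tested members, 15 had a negative log2 fold change, the median was 3.04, and 80 were called higher and 5 lower when adjusted over the list alone, against 0 over all genes tested in edgeR, 82 higher and 5 lower at an unadjusted p under 0.05, and 75 higher and 4 lower in DESeq2. The camera adjusted p was 5.92e-09, and the adjusted p = 0.849 with an estimated correlation. The list did not move as 1 block. The collagen dpy-17 (chromosome III, 5107330 to 5108491) averaged 272 ± 216 CPM on BW25113 and 13.1 ± 10.5 CPM on purE (SD, n = 3), a log2 fold change of -4.37 ± 0.84 with an adjusted p of 0.129 in edgeR and 5.58e-07 in DESeq2. It was -3.64 without BW25113 replicate 1, at 494 CPM, and -5.38 without purE replicate 1, where edgeR called it. Further collagens chosen after their values were seen were rol-6, bli-2 and dpy-13, with log2 fold changes of 5.62 ± 1.48, 5.68 ± 1.43 and 4.84 ± 1.28, and the adult collagen col-19, with 0.02 ± 0.34. The mean of the list was 2.4 in purE replicate 2, 1.38 in purE replicate 3 and -1.11 in purE replicate 1, the last within the range of -0.68 to -1.26 on BW25113. All purE libraries lay above all BW25113 libraries for only 8 of the 129 members, and below for 4. Chance gives 10% on average for both directions together, so the groups were not separated in this list.

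Markers of the early embryo and of oocytes and the hermaphrodite germline fell as groups. All 10 tested embryo markers had a negative log2 fold change, with a median of -0.91, and 4 were called lower when adjusted over the list alone, against 0 over all genes tested in edgeR, 5 at an unadjusted p under 0.05 and 3 in DESeq2. The nuclear receptor gene nhr-25 (chromosome X, 13008493 to 13013964) averaged 4.05 ± 0.93 CPM on BW25113 and 1.41 ± 0.17 CPM on purE (SD, n = 3). Of 36 oocyte and germline markers, 34 had a negative log2 fold change, with a median of -0.39, and oma-1, which acts in oocyte maturation, had -0.62 ± 0.28. All 6 vitellogenins, the yolk proteins, had negative values with a median of -0.55, and the list fell. vit-2 averaged 18768 ± 1244 CPM on BW25113 and 13450 ± 3930 CPM on purE (SD, n = 3), and vit-4 had a log2 fold change of -0.73 ± 0.38. The camera adjusted p was 5.99e-05 for the embryo, 8.34e-05 for the oocyte and 0.0183 for the vitellogenin list, and for each of them the adjusted p = 0.849 with an estimated correlation. The per-library means of the oocyte list were -0.68 in purE replicate 2 but 0.05 and 0.03 in purE replicates 1 and 3, within the range of -0.01 to 0.33 on BW25113, and those of the vitellogenins were -1.02 in purE replicate 2 but 0.0435 and 0.045 in the others, within -0.01 to 0.48. The embryo list was lower in all 3 purE libraries, at -0.22, -1.25 and -0.35 against 0.37 to 0.87. The vitellogenin call was lost without BW25113 replicate 3, at an adjusted p of 0.0782, and without purE replicate 2, at 0.170.

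Genes of purine synthesis and salvage rose as a group. Of 15 tested members, 14 had a positive log2 fold change, the median was 0.40, and for 7 of them all purE libraries lay above all BW25113 libraries. The salvage enzyme gene hprt-1 (chromosome I, 14657355 to 14661495) averaged 6.38 ± 5.64 CPM on BW25113 and 22.6 ± 1.65 CPM on purE (SD, n = 3), a log2 fold change of 1.83 ± 0.56 with an adjusted p of 0.15 in edgeR and 0.0237 in DESeq2. BW25113 replicate 1 stood at 12.9 CPM against 3.18 and 3.05 in the other BW25113 libraries, and the log2 fold change was 2.83 without it and 1.41 without either of the others. Values in the list ran from -0.41 ± 0.39 for pacs-1, the 1 member below 0, and xdh-1, a purine breakdown enzyme, had 0.86 ± 0.36; both were chosen after their values were seen. With fry the adjusted p was 0.101 by direction and 0.0233 in either direction. The camera adjusted p of the list was 0.0282, and the adjusted p = 0.849 with an estimated correlation. That correlation was -0.00333, below the preset 0.01, and the unadjusted camera p was then 0.0479. For the sperm markers the estimated correlation was 0.904. The call was lost without BW25113 replicate 1, BW25113 replicate 2 or purE replicate 1, with adjusted p-values of 0.0638, 0.141 and 0.383, at 0.0749 without a low-count filter and at 0.0894 when libraries were scaled by their size alone.

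Genes of the folate and methionine cycles rose as a group, with 14 of 24 members positive, a median log2 fold change of 0.39 and a camera adjusted p of 0.0394. The adjusted p = 0.849 with an estimated correlation. That correlation was 0.0248. With fry the adjusted p was 0.101 by direction and 0.037 in either direction. When adjusted over the list alone 3 members were called higher, against 0 over all genes tested in edgeR, 10 at an unadjusted p under 0.05 and 3 in DESeq2. These 3 were cth-1, with a log2 fold change of 2.45 ± 0.32, and, named after their values were seen, sams-5, with 2.28 ± 0.60, and gcst-1 of the glycine cleavage system, with 0.84 ± 0.22. The S-adenosylmethionine synthetase gene sams-1 had 0.56 ± 0.35 and an adjusted p of 0.454. The call was lost without BW25113 replicate 1 (adjusted p of 0.185), BW25113 replicate 2 (0.134), purE replicate 1 (0.273) or purE replicate 3 (0.0571), at 0.0837 without a low-count filter and at 0.0565 with scaling by library size alone.

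**Figure D2:**
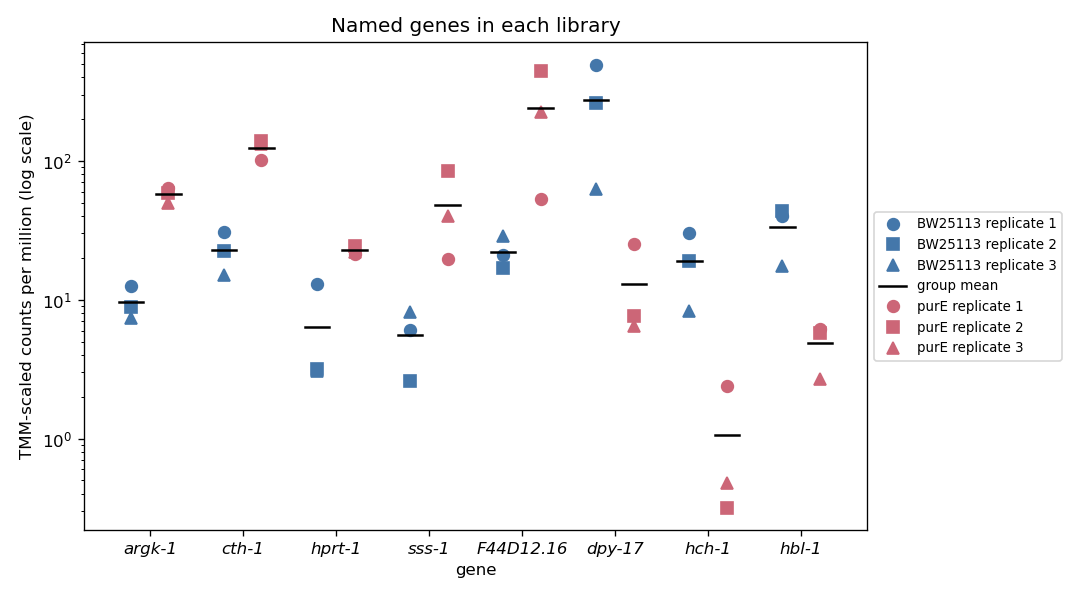
The plot shows CPM scaled with TMM factors on a log axis for 8 named genes in each library, with BW25113 in blue, purE in red, 1 symbol per replicate number and a bar at each group mean. For argk-1 the purE libraries lie between 49.9 and 63.8 CPM and the BW25113 libraries between 7.36 and 12.58 CPM, while for sss-1 the purE libraries spread from 19.7 to 84.5 CPM.

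The genes furthest apart under the naming rule each had an edgeR adjusted p of 0.129. On the higher side stood F44D12.16 with a log2 fold change of 3.43 ± 0.68, F41H10.1 with 3.14 ± 0.60, sss-1 with 3.10 ± 0.61, argk-1 with 2.58 ± 0.29 and cth-1 with 2.45 ± 0.32. DESeq2 called argk-1 at an adjusted p of 1.64e-09 and cth-1 at 6.96e-08. Both genes lie on the forward strand of chromosome V, cth-1 at 16100680 to 16102750 and argk-1 at 16103894 to 16105952, with 1143 bases between them. On the lower side stood dpy-17 with -4.37 ± 0.84, the zinc protease gene hch-1 with -4.12 ± 0.81, the developmental timing gene hbl-1 with -2.78 ± 0.46, Y7A9D.1 with -2.71 ± 0.55 and W04A8.4 with -2.58 ± 0.50. The gene hbl-1 (chromosome X, 5822142 to 5827755) averaged 33.6 ± 14.1 CPM on BW25113 and 4.87 ± 1.91 CPM on purE (SD, n = 3). Without purE replicate 2 the values of F44D12.16, F41H10.1 and sss-1 were 2.65, 2.42 and 2.42, and without purE replicate 1 that of hch-1 was -5.68, called by edgeR, while dpy-17 ranged from -5.38 without purE replicate 1 to -3.64 without BW25113 replicate 1. Without purE replicate 1, edgeR called argk-1 and cth-1, both at an adjusted p of 0.00296.

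A further group of metabolic and defence lists rose by camera. C-type lectins had 64 of 84 members positive, a median log2 fold change of 0.44 and an adjusted p of 0.00170, but an adjusted p = 0.849 with an estimated correlation, and clec-78 went the other way at -2.44 ± 0.52. The nuclear-encoded respiratory chain had 34 of 36 members positive, a median of 0.39 and an adjusted p of 0.00455, but an adjusted p = 0.849 with an estimated correlation, with gas-1 of complex I at 0.75 ± 0.28. Fatty acid synthesis and desaturation had 20 of 24 positive, a median of 0.43 and an adjusted p of 0.00788, but an adjusted p = 0.849 with an estimated correlation, with the low-abundance elongase gene elo-8 at 3.36 ± 0.90, or 2.29 without purE replicate 2. Metal and haem homeostasis had 11 of 14 positive, a median of 0.93 and an adjusted p of 0.00788, but an adjusted p = 0.849 with an estimated correlation. Its haem transporter gene hrg-1, the 1 member called adjusted over the list alone, averaged 13.4 ± 3.19 and 34.5 ± 8.38 CPM (SD, n = 3), whereas the metallothionein mtl-1 had a log2 fold change of -2.39 ± 0.97. Its BW25113 libraries, at 17.4, 7.70 and 0.687 CPM, overlapped the purE libraries at 0.845 to 2.90 CPM, and the value was -1.39 without BW25113 replicate 1, -3.03 without BW25113 replicate 3 and -3.08 without purE replicate 2. Insulin-like peptides had 18 of 23 positive, a median of 0.72 and an adjusted p of 0.0304, but an adjusted p = 0.849 with an estimated correlation. When adjusted over the list alone 4 were called higher and 1 lower, against 0 over all genes tested in edgeR, 7 and 2 at an unadjusted p under 0.05 and 5 and 2 in DESeq2. The 1 called lower was ins-2, at 1.38 ± 0.48 CPM on BW25113 and near the detection floor at 0.138 ± 0.029 CPM on purE (SD, n = 3). Body wall muscle markers (median 0.46, adjusted p of 0.0394), oxidative stress and SKN-1 targets (0.44, 0.0398) and neuron markers (0.53, 0.0398) rose too, and for each of these 3 lists the adjusted p = 0.849 with an estimated correlation. Their members of smallest p were unc-60 at 3.63 ± 1.04, gst-10 at 1.15 ± 0.34 and flp-1 at 1.41 ± 0.41. The gene unc-60 stood at 48.1 and 55.9 CPM in purE replicates 2 and 3. In purE replicate 1 it stood at 1.36 CPM, below the BW25113 libraries at 2.33 to 3.41 CPM. In purE replicate 1 the mean lay within the range of the BW25113 libraries for the respiratory chain (-0.13), metal and haem genes (-0.29), insulin-like peptides (-0.32), muscle markers (-0.26), neuron markers (-0.18) and oxidative stress targets (-0.11). Calls were lost without BW25113 replicate 3 for the respiratory chain (0.414) and insulin-like peptides (0.168), without BW25113 replicate 2 for fatty acid synthesis (0.0951), and without purE replicate 2 for metal and haem genes (0.0771) and insulin-like peptides (0.186). Leaving out single libraries ended the calls of muscle markers in 5 of 6 cases, of neuron markers in 5 and of oxidative stress targets in 4, with adjusted p-values reaching 0.186, 0.396 and 0.770. Those of muscle, neuron and oxidative stress lists also ended without a low-count filter (0.0838, 0.0793 and 0.262) and with library size alone (0.0763, 0.0540 and 0.0565), that of muscle markers with the replicate block (0.0512) and without the 100 most abundant genes (0.106), and that of insulin-like peptides without a low-count filter (0.0707).

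The remaining 19 tested lists did not pass the camera test. Intestinal immune effectors had a median log2 fold change of 0.44 and an adjusted p of 0.0759, with clec-4 at 2.07 ± 0.56 (1.25 without purE replicate 2), and passed without BW25113 replicate 2, at 0.0161, without purE replicate 1, at 0.0470, with library size alone, at 0.0471, and with the replicate block, at 0.0330. Genes that the insulin pathway factor DAF-16 raises had a median of -0.09 (adjusted p of 0.960) and genes it lowers had 0.42 (0.906). Without BW25113 replicate 3 the raised genes were lower as a group at an adjusted p of 0.0443. In those lists aqp-1 had a log2 fold change of 1.58 ± 0.43 and dod-19 averaged 87.1 ± 23.7 CPM on BW25113 and 187 ± 57.3 CPM on purE (SD, n = 3). Longevity regulators had a median of -0.06 (0.345), with pha-4 at -0.99 ± 0.37. The endoplasmic reticulum unfolded protein response had a median of 0.01 and a mean of 0.75 (0.686). Adjusted over the list alone, 7 of its 27 members were called higher, against 0 over all genes tested in edgeR, 7 at an unadjusted p under 0.05 and 7 in DESeq2. The 7 were abu and pqn genes, which encode glutamine- and asparagine-rich proteins, with abu-7 at 3.72 ± 0.94, or 2.90 without purE replicate 2 and 4.37 without BW25113 replicate 3. Mitochondrial unfolded protein response genes had a median of 0.19 (0.445), with timm-17B.1 at 0.69 ± 0.29, and cytosolic heat shock genes had -0.09 (0.445), with F44E5.4 at -0.70 ± 0.54. Intracellular pathogen response genes had a median of 0.34 (0.671), with skr-3 at 0.59 ± 0.32. Epidermal antimicrobial peptides had a median of 0.86 (0.207), with all 10 positive and nlp-33 at 2.24 ± 0.76 (0.97 without purE replicate 2), and passed without purE replicate 1 at 0.0128.

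Lipid breakdown had a median log2 fold change of -0.05, a mean of 0.08 and a camera direction of lower (adjusted p of 0.925). Its member hacd-1, a hydroxyacyl-CoA dehydrogenase, was called adjusted over the list alone and averaged 77.2 ± 2.00 CPM on BW25113 and 164 ± 13.6 CPM on purE (SD, n = 3). Cytochrome P450 enzymes likewise had a positive median of 0.13 and mean of 0.07 with a camera direction of lower (0.906), and cyp-33C8 had 2.51 ± 0.54, or 1.76 without purE replicate 2. UDP-glucuronosyltransferases had a median of 0.04 (0.961), and their camera direction turned lower when libraries were scaled by size alone, with ugt-4 at -1.76 ± 0.44. Pyrimidine and deoxynucleotide metabolism had 0.16 (0.686), with upb-1 at 0.69 ± 0.22, and the propionate and vitamin B12 response had -0.05 (0.686), with pcca-1 at 0.55 ± 0.27. Autophagy and lysosome genes had -0.14 (0.171), passing without BW25113 replicate 3 at 0.0479, and epg-2 was called lower adjusted over the list alone at -2.27 ± 0.46. Cytosolic ribosomal proteins had 0.11 (0.18) and passed without BW25113 replicate 1 at 0.0496 and without the 100 most abundant genes at 0.0391. Their member of smallest p, rpl-42, was near the detection floor on BW25113 at 0.206 ± 0.128 CPM (SD, n = 3), with a log2 fold change of 3.42 that was 2.52 without purE replicate 2. Histones had a median of -0.25 (0.221), and passed as lower without BW25113 replicate 3 at 0.0171 and without purE replicate 2 at 0.0448. The linker histone gene his-24, filed in that list, averaged 551 ± 215 CPM on BW25113 and 115 ± 2.15 CPM on purE (SD, n = 3) and was called adjusted over the list alone. Pharynx markers had 0.73 (0.298) and passed with the filter of 1 CPM in 3 libraries at 0.0452, with phat-6 at 1.12 ± 0.37, and intestine markers had 0.33 (0.224), with gcst-1 again of smallest p. In the 24 lists with 0 members called by edgeR adjusted over the list alone, 92 of 653 tested members had an unadjusted p under 0.05 and DESeq2 called 29.

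With all 6 libraries, none of the tested reporter genes fixed for reporting in any case passed edgeR's adjusted threshold, though DESeq2 called mtl-1 at 0.0426. Log2 fold changes were 0.30 ± 0.47 for sod-3, 1.18 ± 0.44 for gst-4, 0.28 ± 0.24 for hsp-6, -0.30 ± 0.31 for hsp-4, 0.35 ± 0.32 for fat-7, -0.08 ± 0.52 for acdh-1, -0.08 ± 0.68 for irg-4 and -0.17 ± 0.53 for T24B8.5. The edgeR adjusted p was smallest for gst-4, at 0.220. With 1 library left out, gst-4 had 0.58 without purE replicate 2 and 1.39 without purE replicate 1, where edgeR called it. The value of sod-3 was 0.89 without BW25113 replicate 1 and -0.13 without BW25113 replicate 2. That of acdh-1 was -0.87 without purE replicate 1 and 0.35 without purE replicate 2, and that of T24B8.5 was 0.47 without BW25113 replicate 2. The value of irg-4 was 0.52 without BW25113 replicate 1, 0.15 and 0.20 without purE replicates 1 and 3, and -1.01 without purE replicate 2. The heat shock gene hsp-16.2, at 0.265 ± 0.210 CPM on BW25113 and 0.398 ± 0.187 CPM on purE (SD, n = 3), and pals-5, at 0.090 ± 0.090 and 0.018 ± 0.030 CPM, were too low to be tested.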

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

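The settings that used the sperm markers as a covariate, the FPKM values, DESeq2 with libraries left out, the lists without the 100 most abundant genes, and the robust and older edgeR forms were chosen after the result was seen. The count of genes called by edgeR was 0 under every scaling and filter tried, with limma-voom, with FPKM values, with the covariate and with 5 of the 6 libraries left out in turn, while the count at an unadjusted p under 0.05 was 2004 in the main setting, 1285 with FPKM values and 313 with the covariate. It was 946 with DESeq2 and ranged from 0 to 1852 with 1 library left out, the highest without purE replicate 1. With 1 library left out the unadjusted count ranged from 1267 to 4273 and the DESeq2 count from 259 to 2574. Among 1051 values of 53 named genes under the alternatives, 976 kept their direction and side of the threshold, 60 passed it anew and 15 turned direction. The median log2 fold change of all genes moved by -0.14 with limma on the FPKM values, which also changed the test and the filter, and by less than 0.1 with the other scalings of the counts. The cause of the changes given here was not tested. Leaving out a library or adding a covariate leaves less data per estimate. Yet without purE replicate 1 the edgeR counts rose, to 1852 called and 4273 at an unadjusted p under 0.05. Depth limits genes near 0.13 CPM, such as hsp-16.2 and pals-5.

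The replicate numbers did not pair the samples throughout. The bound set for pairing, a correlation of 0.1, was passed by replicate 3 and missed by replicates 1 and 2. A shared batch or day, on which the labels are silent, cannot be excluded in this way. The deviations of same-numbered libraries from their group means correlated at -0.137, -0.170 and 0.136 for replicates 1, 2 and 3, and purE replicates 1, 2 and 3 correlated best with BW25113 replicates 2, 1 and 3. With the replicate number as a block edgeR called 2 genes, hil-7 at a log2 fold change of -4.29 and col-165 at -6.15, both with an adjusted p of 0.0187 and both named after their values were seen. Under the block the intestinal immune effectors passed at 0.0330, body wall muscle markers missed at 0.0512, and UDP-glucuronosyltransferases turned lower at 0.888.

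Of the 34 lists, camera called 15 in the main setting, 9 without a low-count filter, 3 of 33 with the covariate, which is itself the mean of the sperm list, and 0 of 34 with an estimated correlation, where each of the 15 had an adjusted p of 0.849. In either direction fry called 4 lists, at adjusted p-values of 0.0233 for purine, 0.037 for folate and 0.0435 for both insulin-like peptides and UDP-glucuronosyltransferases. Sperm markers had 0.155 and collagens 0.254 in that test. By direction fry called 0 lists. Its adjusted p-values were 0.393 for vitellogenins, collagens, oocyte markers, oxidative stress targets, the respiratory chain, muscle and neuron markers, 0.305 for sperm markers and C-type lectins, 0.226 for embryo markers, 0.101 for purine and folate genes, 0.420 for insulin-like peptides, 0.269 for fatty acid synthesis and 0.388 for metal and haem genes. fry turned the direction of the genes raised by DAF-16 (0.929), P450 enzymes (0.790) and lipid breakdown (0.798), none of which passed in either test.

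Without a low-count filter the lists that missed were purine (0.0749), folate (0.0837), insulin-like peptides (0.0707), oxidative stress targets (0.262), muscle (0.0838) and neuron markers (0.0793), and the pathogen response (0.554) and UDP-glucuronosyltransferases (0.516) turned direction. With library size alone purine (0.0894), folate (0.0565), oxidative stress (0.0565), muscle (0.0763) and neuron lists (0.0540) missed, intestinal immune effectors passed (0.0471), and UDP-glucuronosyltransferases turned (0.845). With at least 1 CPM in 3 libraries pharynx markers passed (0.0452), and the lists raised (0.949) and lowered (0.763) by DAF-16 and lipid breakdown (0.925) turned direction. With the 100 most abundant genes left out muscle markers missed (0.106) and ribosomal proteins passed (0.0391), and vitellogenins had too few members left to test.

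With the covariate the collagens turned lower at 1.80e-21 and epidermal antimicrobial peptides at 0.00114, both with an adjusted p = 0.933 with an estimated correlation, and oocyte markers turned higher at 0.682. Calls were lost for vitellogenins (0.988), embryo markers (0.0905), folate genes (0.0905), C-type lectins (0.241), fatty acid synthesis (0.506), the respiratory chain (0.452) and oxidative stress targets (0.394). Lists that turned lower were insulin-like peptides (0.506), immune effectors (0.591), the pathogen response (0.903), UDP-glucuronosyltransferases (0.656), the endoplasmic reticulum response (0.177), metal and haem genes (0.728), ribosomal proteins (0.0905), muscle (0.506), neuron (0.241), pharynx (0.599) and intestine markers (0.452). Lists that turned higher were P450 enzymes (0.251), heat shock genes (0.394), the propionate response (0.0630) and lipid breakdown (0.506). Log2 fold changes that turned were -0.97 for nlp-33, -0.25 for abu-7, -0.0039 for pcca-1, -0.16 for elo-8, -1.09 for unc-60, -0.23 for gst-4, 0.22 for hsp-4, 1.14 for acdh-1 and -0.33 for sams-1.

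With 1 library left out the adjusted p ranged from 0.0144 to 0.383 for purine, 0.0144 to 0.273 for folate, 0.00654 to 0.170 for vitellogenins, 0.0179 to 0.186 for insulin-like peptides, 0.00684 to 0.0951 for fatty acid synthesis, 0.00925 to 0.0771 for metal and haem, 0.000608 to 0.414 for the respiratory chain, 0.0258 to 0.770 for oxidative stress, 0.0470 to 0.186 for muscle and 0.0254 to 0.396 for neuron lists, with no change of direction. The called lists of sperm (at most 1.78e-08), collagens (1.34e-05), embryo (0.000608), oocyte (0.0448) and C-type lectins (0.0190) passed in all 6 cases. Of lists not called in the main setting, the range was 0.0161 to 0.799 for immune effectors, 0.0479 to 0.220 for autophagy and 0.0171 to 0.738 for histones. Lists that turned direction at least once ranged from 0.0443 to 0.975 for genes raised by DAF-16, 0.726 to 0.963 for genes it lowers, 0.486 to 0.992 for the pathogen response, 0.0128 to 0.772 for epidermal peptides, 0.469 to 0.975 for P450 enzymes, 0.353 to 0.804 for UDP-glucuronosyltransferases, 0.414 to 0.762 for the endoplasmic reticulum response, 0.498 to 0.884 for pyrimidine, 0.250 to 0.804 for propionate, 0.148 to 0.975 for lipid breakdown and 0.0496 to 0.753 for ribosomal proteins. Log2 fold changes ranged from -0.13 to 0.89 for sod-3, -0.87 to 0.35 for acdh-1, -1.01 to 0.52 for irg-4 and -0.56 to 0.47 for T24B8.5.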

Other observations

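Families of genes sharing a name prefix were examined after the result was seen, and all tests of this part except those on spe genes, eggshell genes and exon length matched to sperm and collagen genes were also chosen after it. Of 102 families with at least 10 tested members, camera called 37, and 0 with an estimated correlation, where the smallest adjusted p was 0.742. F-box genes of the fbxb family were lower on the purE diet in all 30 tested members, with a median log2 fold change of -2.27 and an adjusted p of 1.40e-22, an adjusted p = 0.742 with an estimated correlation, and 22 members at an unadjusted p under 0.05. In purE replicate 1, whose collagen mean lay within the BW25113 range and whose sperm mean lay above it, the family was lower too. Its mean log2 CPM relative to each gene's mean was -0.52 there, -2.0 and -0.51 in the other purE libraries, and 1.37, 1.15 and 0.51 on BW25113. The related fbxc family had 20 of 22 members negative, a median of -0.94 and an adjusted p of 2.46e-06. The homeobox genes named ceh had 32 of 38 members negative, a median of -0.66 and an adjusted p of 7.38e-07, and the sdz genes, named for their dependence on SKN-1 in the zygote, had 10 of 12 negative, a median of -2.34 and an adjusted p of 1.69e-05. The adjusted p was 0.742 with an estimated correlation for fbxc, ceh and sdz alike. The larger fbxa family did not pass, with 40 of 64 members negative, a median of -0.10, an adjusted p of 0.147 and 1 member at an unadjusted p under 0.05.

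On the higher side stood neuropeptide families. All 30 flp genes had positive log2 fold changes, with a median of 0.88 and an adjusted p of 5.22e-06, and 60 of 62 nlp genes did, with a median of 0.70 and an adjusted p of 2.48e-05. All 12 fipr genes, which encode small secreted peptides, were positive with a median of 1.70 (adjusted p of 0.000177), all 10 grl genes with 3.25 (0.00458), and 12 of 14 astacin proteases named nas with 1.15 (0.00336). In purE replicate 1 the family mean lay within the BW25113 range for flp (-0.30), nlp (-0.41) and nas (-0.34), below it for grl (-1.31) and above it for fipr (-0.50), so the higher values of flp, nlp, nas and grl came from purE replicates 2 and 3. For each of these families the adjusted p was 0.742 with an estimated correlation. Directions of all families named here were the same with library size alone, with the size factors of DESeq2 and with upper-quartile factors. The F-box families hold close copies, so values of single members are uncertain.

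By group, camera with the preset correlation called sperm and collagen genes higher and embryo and oocyte genes lower on the purE diet. For each of these 4 lists the adjusted p = 0.849 with an estimated correlation. The collagens were high in purE replicates 2 and 3 and the oocyte genes low in purE replicate 2, with the other purE libraries within the BW25113 range. A few abundant genes taking most of the counts do not account for this. All 4 lists kept their direction and passed with the 100 most abundant genes left out. Gene length bias does not account for the collagen and embryo genes. Genes outside the lists matched on exon length had median log2 fold changes of 0.0392 (sperm and collagens together) and 0.0314 (embryo). With 21 sperm genes beside 129 collagens in that match, length bias in the sperm genes was not tested alone and stays open. For the oocyte genes the matched median of -0.0671 was too uncertain beside their own -0.39 to decide. A candidate explanation is a share of younger or less gravid animals in purE replicates 2 and 3, although the oocyte genes and vitellogenins of purE replicate 3, at 0.03 and 0.045 within the BW25113 range, and the embryo genes of purE replicate 1, at -0.22 below all BW25113 libraries, do not go with it. It was tested on other genes of the same kinds in the same libraries. The median of 9 spe genes, 0.98 with 6 positive and 3 negative, lay at percentile 99.12 of matched random sets. The explanation needs this, but with sperm markers already higher in these libraries, spe genes could rise under any cause. The random sets, matched on mean CPM, also leave out the correlation between such genes. The spe percentile therefore does not decide. That of 10 eggshell genes, -0.28 with all 10 negative, lay at percentile 5.02. The eggshell value missed its bound of 5 by less than the sampling error of the random sets, 0.22, an allowance made after the value was seen. The explanation therefore stays open, and an effect of the diet on the worms' own development cannot be told apart from a difference in age at harvest.

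Purine genes were higher in all 3 purE libraries, purE replicate 1 included. A few abundant genes do not account for this, since the median log2 fold change was 0.32 with the 100 most abundant genes left out, against 0.40 with them. The sperm markers were used as a covariate to stand in for stage, which they were not shown to measure. With it the list still passed camera, at an adjusted p of 0.00897, and its median was 0.34. But the adjusted p = 0.933 with an estimated correlation (0.05005 unadjusted). The covariate took the collagens from 3.04 to -0.741. In purE replicate 1 the purine mean was 0.31 beside a sperm mean of -0.46, itself above all BW25113 libraries. That median and purE replicate 1 go against a stage difference as the whole source, but they are not separate evidence. Sperm means of 2.41 and 1.41 set the other purE libraries apart, so the covariate fit rests mostly on purE replicate 1. A stage difference is not excluded. The bound for excluding it, set after the result was seen, asked for a camera p under 0.05 with an estimated correlation. At 0.05005 it was narrowly missed, and 1 library decides nothing. The adjusted 0.933 was shared with most other lists, so it says little about this one.

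For the folate and methionine genes the covariate lowered the median log2 fold change from 0.39 to 0.199 and ended the call, at an adjusted p of 0.0905. The median standard error of single members grew from 0.282 to 0.418, and for the purine genes it grew from 0.257 to 0.415. These errors of single genes do not measure the error of a list median. A stage difference between libraries, itself not established, may thus account for part of the change, and the 6 libraries are too few to separate the parts. The covariate is the mean of the sperm list and was not shown to measure stage. The gene cth-1 and its neighbour argk-1 had log2 fold changes of 2.24 and 2.79 with the covariate, against 2.45 and 2.58 without it.

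The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count called by edgeR was 0 in the real split and in all 10, the highest of the others being 0. The count at an unadjusted p under 0.05 was 2004, with 2218 the highest of the others, and 2 of the 10 splits gave as many. The DESeq2 count was 946, with 556 the highest of the others, and 1 of the 10 gave as many, the real one. For lists the count was 15, with 16 the highest of the others, and 3 of the 10 gave as many. The purine list had an adjusted p of 0.0282 in the real split, and 2 splits with mixed diets gave 0.0222 and 0.016. The split with 2218 genes and 16 lists set BW25113 replicate 1 and purE replicates 2 and 3 against the rest.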
